A study of Homo sapiens with 8 samples.

How the data were processed

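The data are RNA-seq libraries of EndoC-βH1, a human pancreatic beta cell line, reverse transfected for 72 h with small interfering RNA (siRNA) at 15 nmol/L. Per the labels' protocols, 4 libraries came from cells given a pool of non-targeting control siRNAs and 4 from cells given a pool of siRNAs against KCTD17. Total RNA was purified on columns after phenol extraction, and the libraries were made with a kit that marks the strand, per the labels' protocols. How ribosomal RNA was removed, and whether poly(A) RNA was selected, is not given in the sources used here.

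The deposited table holds estimated counts per gene, made by the authors with kallisto on the GRCh38 build, per the submitters' processing notes, which give no version, annotation release or strand setting. The values were tested on the table itself: 26.99% of them were not whole numbers, so they were read as estimated counts that the authors summed per gene. No normalization of these counts is recorded. The table has 65969 Ensembl genes and 16 columns of counts. Only the 8 columns that the labels map to a sample were used, and the other 8 columns were left out because no label describes them.

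Gene symbols were matched for 41981 of the genes from a table of gene names, and 57470 genes were found in the GENCODE release 29 primary annotation, which supplied gene types and coordinates. Estimated counts were rounded and filtered with filterByExpr (minimum count 10, minimum total count 15), which kept 19438 genes. Of these, 912 had values identical to those of another gene ID, so reads may have been split between copies and their levels are uncertain. Because the strand setting is not stated, reads of overlapping and antisense genes cannot be told apart either.

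Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (two-sided, TMM normalization, group as the only term), with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Fold changes are KCTD17 siRNA over control siRNA on the log2 scale, and the standard error (SE) is the fold change divided by the square root of F. CPM values are counts scaled to library size with the TMM factors. A set of 29 gene lists was fixed before the data were examined, and lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over all lists. The separation of the groups was tested on the first principal component of the 500 most variable genes with an exact permutation test over 70 splits, for which the smallest possible p is 0.0286. R 4.3.3 was used.

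Genes named in the text were chosen by a rule also fixed before the data were examined. It takes KCTD17, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 1 CPM and no overlap of the groups, 17 genes fixed by name, up to 4 members with the smallest p of each list described, and the 8 genes with the smallest p. Genes without a symbol and pseudogenes were passed over among the largest changes, which skipped 8 genes on the higher side and 4 on the lower side.

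Depth was 11369874 to 13279770 estimated counts per library, so 1 CPM stands for 11.4 to 13.3 counts. Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom 3.11 to 6.08 over 16540 genes), so none was taken as a duplicate. The labels give no batch or date. The control libraries are numbered 1 to 4 and the KCTD17 siRNA libraries 13 to 16, so the groups share no replicate number and the order of the libraries cannot be told apart from the group. The labels do not say whether the 4 libraries of a group are separate cultures or experiments. The p-values therefore measure only the spread between these libraries, which may be technical.

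The test was checked on simulated counts drawn from the real means, dispersions and library sizes for this 4 against 4 comparison, with 200 changed genes among 19292. It recovered 40.0% of the genes changed by 1.25-fold, 64.0% at 1.5-fold, 76.0% at 2-fold and 98.0% at 4-fold, with 21 calls among 19072 unchanged genes. The changed genes were drawn only above a floor of mean expression, so recovery of the lowest genes kept was not checked. Their share was also far below the 15.0% of genes called in the data. The recovery first required of this check at 2-fold was not met, and the requirement was then moved to 4-fold. A simulated list shifted by 0.3 on the log2 scale was called by camera, and an unshifted one was not. The simulated genes were drawn independently of each other, so this does not check the preset correlation.

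Alternatives fixed before the data were examined were RLE size factors, library size only, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (at least 1 CPM in at least 4 libraries), a test against a fold change of 1.2, an adjusted p of 0.01, leaving out each library, 1 surrogate variable from sva 3.50.0, camera with an estimated correlation, fry, and principal components of 2000 or all genes. A transcript-level test does not apply to this gene-level table. Alternatives chosen after seeing the data were a correction for GC content, protein-coding genes only, genes of the GENCODE release 29 primary annotation only, and leaving out genes that hold 1 of 6 motifs in their 3' UTR.

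The motif scan used GENCODE release 29. For 10953 protein-coding genes with a mean of at least 5 CPM and an annotated 3' UTR of at least 50 bases, KCTD17 left out, the log2 fold change (limited to 1.5 in either direction) was regressed on the presence of each of 15857 7-base sequences found in at least 100 genes. The model held 3' UTR length, dinucleotide shares and transcript GC content. Scanning repeatedly and adding the strongest sequence to the model each time gave the 6 motifs. In 20 simulations with an implanted effect of -0.05, the implanted sequence ranked first each time.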

Results

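The series profiled the RNA of EndoC-βH1, a human pancreatic beta cell line that makes and secretes insulin, after an siRNA pool against KCTD17. KCTD17 is an adaptor of CUL3 ubiquitin ligases, which mark proteins for degradation. There were 8 libraries in 2 groups, 4 with control siRNA and 4 with KCTD17 siRNA. Total estimated counts were 12529743, 13279770, 13102527 and 12807057 in control replicates 1 to 4, and 11543434, 12026280, 12750997 and 11369874 in KCTD17 siRNA replicates 13 to 16. The group means were 12929774 ± 330366 and 11922646 ± 618133 (SD, n = 4 each; exact permutation test, two-sided, p = 0.0571). Protein-coding genes took 75.4% ± 0.717 of the counts in the control libraries and 77.2% ± 0.239 in the KCTD17 siRNA libraries (SD, n = 4 each; exact permutation p = 0.0286, the smallest this design can give). Values below are means ± SD over the 4 libraries of a group.

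The comparison asks which transcripts change when KCTD17 is lowered in a human beta cell line. KCTD17 itself (ENSG00000100379; chromosome 22, 37051736 to 37063390, GRCh38) was lower in all 4 KCTD17 siRNA libraries. Its estimated counts were 84, 106, 97 and 116 in the control libraries and 33, 39, 35 and 34 in the KCTD17 siRNA libraries. Poisson 95% intervals, which cover counting error only, ran from 67.0 to 104.0 for the lowest control count and from 27.7 to 53.3 for the highest KCTD17 siRNA count. The mean fell from 7.93 ± 1.15 to 2.93 ± 0.193 CPM, a log2 fold change of -1.43 (SE 0.17; edgeR, adjusted p = 5.3e-05), which left 37.1% of the control level.

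**Figure D1:**
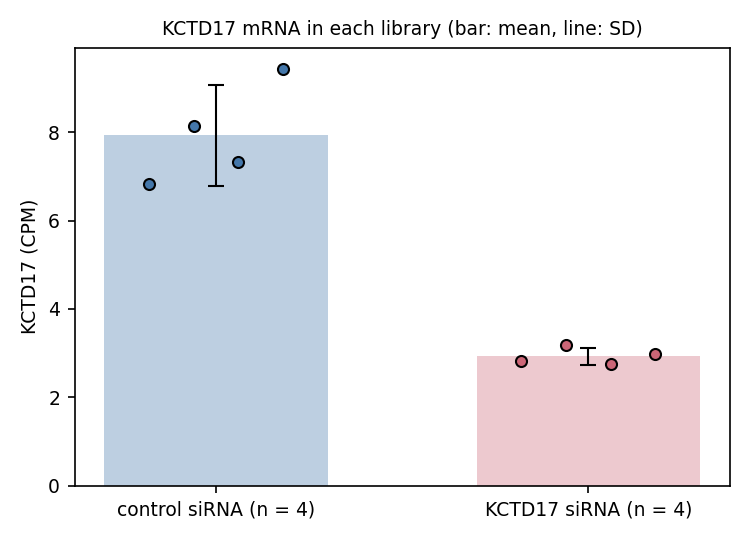
KCTD17 in CPM (vertical axis) for each library; bars are group means, lines are SD and points are the 4 libraries of each group. The KCTD17 siRNA libraries lie between 2.75 and 3.19 CPM, all below the control libraries at 6.82 to 9.44 CPM.

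Beside KCTD17, 3 gene lists passed the threshold: 15 of 21 genes in the list of unfolded protein response chaperones were higher, 17 of 30 proliferation genes were higher and 2 lower, and 9 of 23 genes of cholesterol synthesis were lower and 1 higher. None of the 3 lists passed with an estimated correlation (camera, adjusted p = 0.397, 0.641 and 0.676). No difference in insulin RNA was detectable. Of 19438 genes tested, 2914 passed the threshold (edgeR, adjusted p below 0.05), of which 1389 were higher and 1525 lower with KCTD17 siRNA. With scaling by library size only, 1956 were higher and 1277 lower. Most changes were small: the median size of the log2 fold change among called genes was 0.33, and 108 genes changed more than 2-fold, 65 of them upward. Among the called genes 2676 had no overlap between the groups, and over all tested genes that share was 19.4%, against 2.86% by chance.

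The 8 genes with the smallest p included 3 that rose and are not histones. APLP2, a relative of the amyloid precursor protein, rose from 391 ± 16.5 to 760.5 ± 23.4 CPM (log2 fold change 0.96, SE 0.04, edgeR adjusted p = 9.0e-09). P4HB, a protein disulfide isomerase, rose by 0.60 and ANKRD52 by 0.81 on the log2 scale. Replication histone genes took 3 of the 8 places: H2BC14 (log2 fold change 1.88, SE 0.05), H2AC8 (1.23, SE 0.06) and an H2A gene without a matched symbol (ENSG00000272196; 1.01, SE 0.05). They belong to a family of near-identical genes, so their single levels are uncertain. NCR3LG1, a ligand of a natural killer cell receptor, fell from 91.8 ± 4.14 to 48.9 ± 0.94 CPM (log2 fold change -0.91) and HS6ST3, a heparan sulfate sulfotransferase, from 169 ± 4.20 to 98.4 ± 3.84 CPM (-0.78).

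Among the genes with the largest rise, KLF15, a transcription factor of metabolic genes, went from 4.32 ± 1.04 to 13.5 ± 1.03 CPM (log2 fold change 1.65, SE 0.16). Among those with the largest fall, the lysosomal glycoprotein CD68 went from 54.2 ± 4.22 to 22.6 ± 2.97 CPM (-1.27, SE 0.09). The small GTPase RHOC changed by -1.34 (SE 0.16), the collagen gene COL16A1 by -1.61 (SE 0.26), the transporter SLC47A1 by -1.32 (SE 0.25), CEND1 by -1.32 (SE 0.27) and S100A4 by -1.23 (SE 0.30). ACY3 (-1.26), SNORD68 (-1.55) and DERPC (-1.30) also fell, and CCN3 (1.77), H2BC26 (1.56) and H2AC25 (1.45) rose. The histone pair has values identical to those of another gene ID, so these levels are uncertain, and DERPC is outside the GENCODE release 29 annotation. DESeq2, which filters on the mean count, gave no adjusted p for CCN3, SLC47A1, S100A4 and SNORD68.

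The other genes with the largest changes had a mean of a few CPM, and each lost its call without at least 1 library. CFC1B (log2 fold change 2.71, SE 0.69), which shares reads with its near-identical copy CFC1, lost it without KCTD17 siRNA replicate 14 (adjusted p up to 0.0586) and was at 3.35 without control replicate 2. The read-through gene ARHGAP19-SLIT1 (1.40) lost it without KCTD17 siRNA replicate 14 (adjusted p up to 0.0719), PAPPA2 (1.33) without control replicate 2 or KCTD17 siRNA replicate 13 (adjusted p up to 0.0592), and PWRN4 (1.37) without control replicate 4 or KCTD17 siRNA replicate 16 (adjusted p up to 0.0839). SNORA6 (-1.27) lost it without control replicate 1 or KCTD17 siRNA replicates 14 or 16 (adjusted p up to 0.0674) and DNAI3 (1.31) without control replicates 1 or 3 or KCTD17 siRNA replicates 13 or 16 (adjusted p up to 0.0883). The antisense gene L3MBTL2-AS1 (1.32) lost it without control replicates 1, 2 or 3 or KCTD17 siRNA replicates 14 or 16 (adjusted p up to 0.0674). LRRIQ1 (1.36) lost it without control replicates 1 or 2 or KCTD17 siRNA replicates 14, 15 or 16 (adjusted p up to 0.0717). FAM220A (-2.08) lost it without control replicates 2 or 3 or KCTD17 siRNA replicates 13, 14, 15 or 16 (adjusted p up to 0.128).

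**Figure D2:**
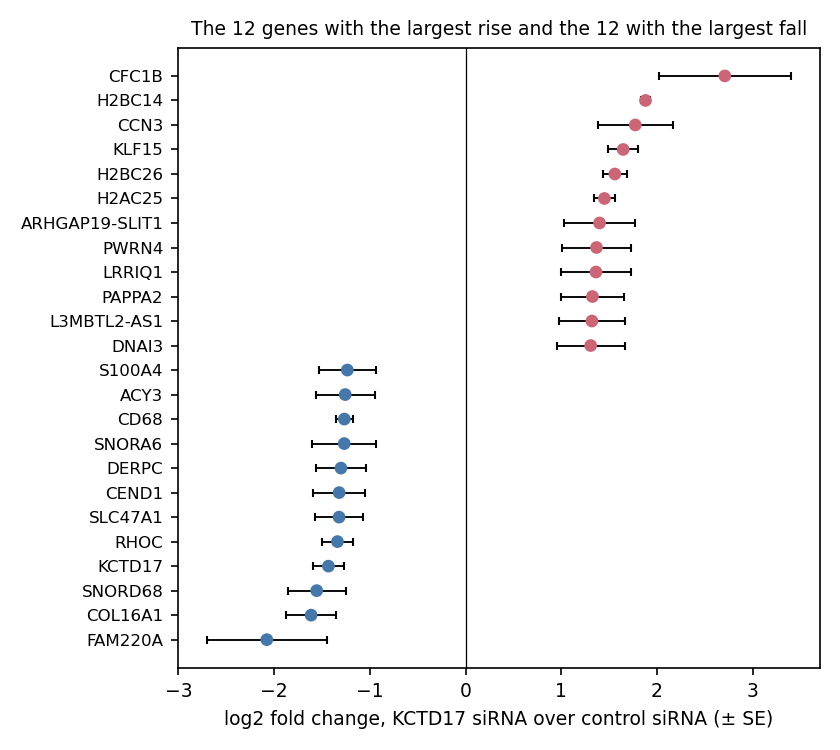
Log2 fold change of the 12 genes with the largest rise and the 12 with the largest fall (horizontal axis, KCTD17 siRNA over control siRNA); points are edgeR estimates and lines are SE. Estimates run from -2.08 (FAM220A) to 2.71 (CFC1B), and KCTD17 lies at -1.43.

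Of the 29 lists, 27 had enough measured members and 3 passed the threshold. The list of unfolded protein response chaperones was higher (camera, adjusted p = 9.2e-09; adjusted p = 0.397 with an estimated correlation), with 15 of 21 members higher and 17 when adjusted over the list alone. Such chaperones fold proteins in the endoplasmic reticulum, and the list also holds other genes of the response, such as XBP1 and ERN1. MANF, a secreted stress-induced protein, rose from 80.1 ± 4.18 to 133 ± 3.27 CPM (log2 fold change 0.73, SE 0.05, edgeR adjusted p = 3.3e-07). PDIA4 rose by 0.35, HYOU1, which has an identical copy, by 0.35 and HSPA5, a major chaperone of this compartment, by 0.30.

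The proliferation list was also higher (camera, adjusted p = 9.6e-06; adjusted p = 0.641 with an estimated correlation), with 17 of 30 members higher and 2 lower, or 19 and 5 when adjusted over the list alone. TOP2A, which untangles chromosomes, rose from 473 ± 10.9 to 625 ± 5.57 CPM (log2 fold change 0.40), and the genes of mitosis BUB1, TPX2 and BUB1B rose by 0.53, 0.35 and 0.47. The 2 members that fell, MCM3 (-0.23) and MCM6 (-0.17), are parts of the replicative helicase. They lie outside the rule for named genes and were chosen after their values were seen.

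Cholesterol synthesis was lower (camera, adjusted p = 0.00146; adjusted p = 0.676 with an estimated correlation), with 9 of 23 members lower and 1 higher, or 10 and 1 when adjusted over the list alone. SC5D fell from 131 ± 5.43 to 91.2 ± 1.61 CPM (log2 fold change -0.52) and MSMO1 changed by -0.40, both enzymes late in the pathway. INSIG1, which retains the activator of this pathway in the endoplasmic reticulum, rose by 0.25. The list lost its call without the genes whose 3' UTR holds 1 of 6 motifs described in the closing observations (15 members left, adjusted p = 0.245).

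**Figure D3:**
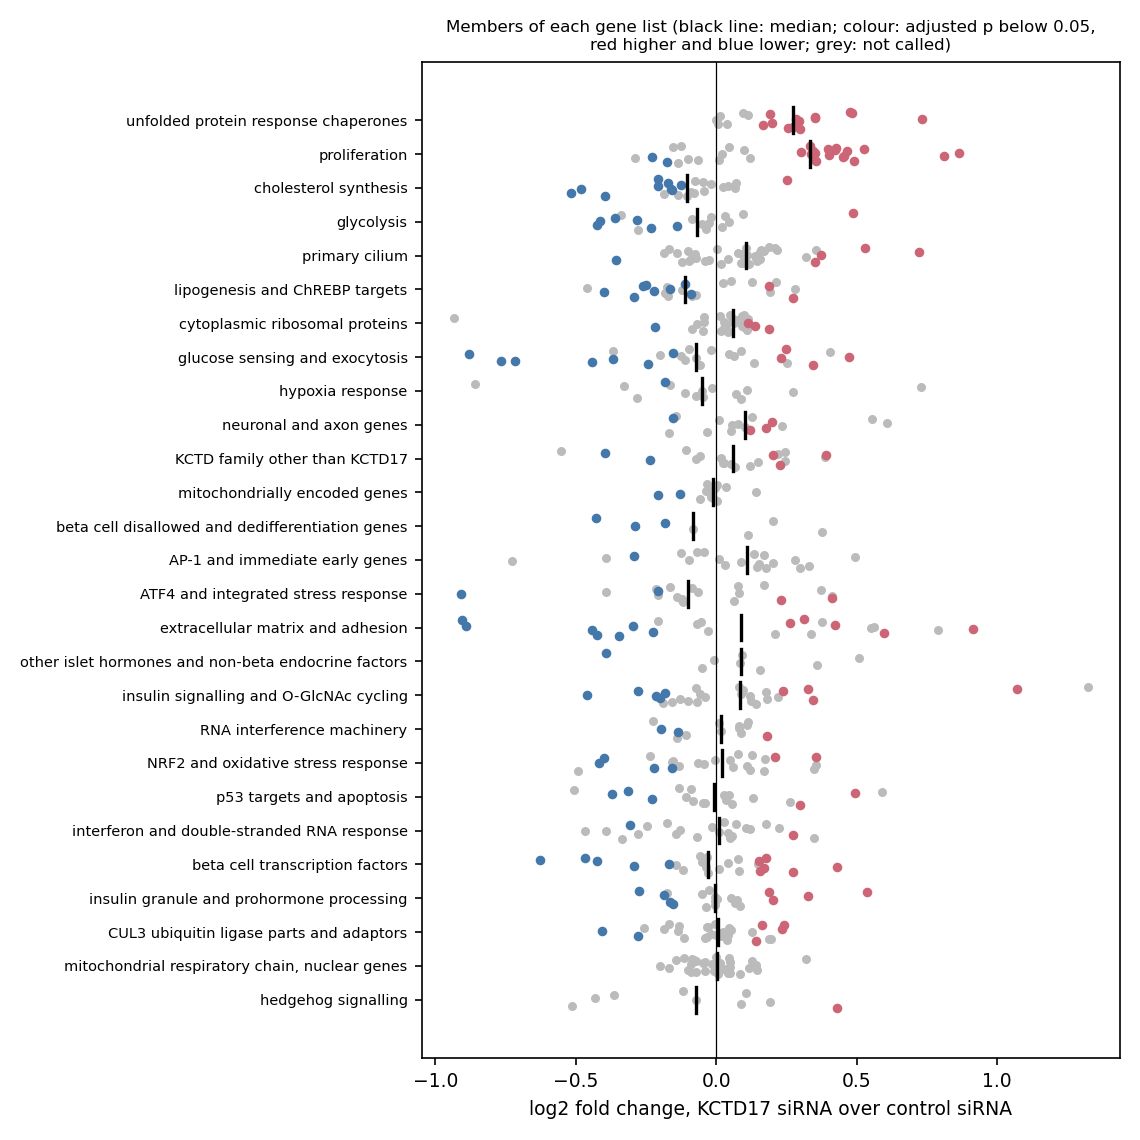
Log2 fold change of every measured member of the 27 tested gene lists (horizontal axis, KCTD17 siRNA over control siRNA); points are genes, red higher and blue lower at adjusted p below 0.05 (edgeR), and black lines are list medians. The proliferation list has the highest median, 0.33, with 17 of its 30 members called higher.

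Genes of glucose sensing and insulin release went both ways, with 4 of 25 members higher and 7 lower (4 and 8 when adjusted over the list alone; camera, adjusted p = 0.243). G6PC2, a glucose-6-phosphatase of islets, fell from 44.9 ± 4.41 to 24.4 ± 3.61 CPM (log2 fold change -0.88, SE 0.10, edgeR adjusted p = 3.8e-05), and the exocytosis gene STX1A changed by -0.44. SYT4 rose by 0.47. The glucose transporter gene SLC2A2 was at 2.63 ± 0.444 and 2.04 ± 0.213 CPM (-0.37, adjusted p = 0.332).

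Transcription factors of the beta cell were split as well, with 6 of 23 higher and 5 lower (6 and 7 when adjusted over the list alone; camera, adjusted p = 0.862). MAFA (-0.47, SE 0.06), NKX6-1 (-0.42, SE 0.05) and PDX1 (-0.17, SE 0.03), which maintain the mature beta cell, fell (edgeR, adjusted p = 1.2e-04, 4.5e-05 and 0.00415). MLXIPL, the glucose-responsive factor ChREBP, rose by 0.27 and RFX6 by 0.18. NEUROD1 was higher by 0.15 (adjusted p = 0.0234), a call lost without control replicates 1, 3 or 4 or KCTD17 siRNA replicates 14, 15 or 16 (adjusted p up to 0.0743).

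INS was at 9636 ± 362 and 9461 ± 272 CPM (log2 fold change -0.03, SE 0.03, edgeR adjusted p = 0.629), and part of its reads may be counted for the read-through gene INS-IGF2. IAPP was at 23.7 ± 3.75 and 23.8 ± 3.24 CPM (adjusted p = 0.989), and no difference was detectable in either. In the list of insulin granule genes 4 of 20 members were higher and 4 lower (4 and 5 when adjusted over the list alone; camera, adjusted p = 0.862). SCG2 rose by 0.54, PAM by 0.33 and CPE by 0.20, and ERO1B changed by -0.15.

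Insulin signalling genes changed in both directions, with 4 of 28 higher and 5 lower (8 and 5 when adjusted over the list alone; camera, adjusted p = 0.837). The kinase gene AKT1 fell from 263 ± 18.1 to 192 ± 6.81 CPM (log2 fold change -0.46, SE 0.05) while AKT2 rose by 0.35. IRS2 rose by 0.33 and INSR, the insulin receptor, changed by -0.28. FOXO1 was lower by a log2 fold change of -0.18 (edgeR, adjusted p = 0.0322), a call lost without control replicates 1 or 2 or KCTD17 siRNA replicates 13, 14 or 15 (adjusted p up to 0.0975). OGA (0.08, adjusted p = 0.247) did not pass, nor did the phosphatase gene PHLPP2 (-0.19, adjusted p = 0.132), which passed without KCTD17 siRNA replicate 13 (-0.26).

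In lipogenesis 2 of 23 members were higher and 8 lower (3 and 9 when adjusted over the list alone; camera, adjusted p = 0.104), with FADS1, ELOVL5, ACLY and ACSS2 at -0.26, -0.29, -0.22 and -0.40. In glycolysis 1 of 18 was higher and 6 lower (1 and 6 when adjusted over the list alone; camera, adjusted p = 0.104), with LDHB, PFKL and PFKFB4 at -0.41, -0.36 and -0.28 and BPGM at 0.49. In extracellular matrix and adhesion 5 of 22 were higher and 7 lower (6 and 7 when adjusted over the list alone; camera, adjusted p = 0.837). The paired basement membrane genes COL4A1 and COL4A2 fell from 24.8 ± 0.874 to 13.2 ± 0.869 CPM and from 157 ± 10.1 to 84.7 ± 4.96 CPM (log2 fold changes -0.90 and -0.89), CDH1 changed by -0.43 and LAMC1 by 0.42.

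KCTD17 is known to act on cilia through the TCHP protein, whose level was not measured here. The RNA of TCHP was at 43.5 ± 3.06 and 39.5 ± 5.30 CPM (log2 fold change -0.14, edgeR adjusted p = 0.34). In the primary cilium list 4 of 41 members were higher and 1 lower, the same counts when adjusted over the list alone (camera, adjusted p = 0.104). With fry, 1 of the alternatives, the list passed as higher (adjusted p = 0.0111). AURKA rose by 0.35 and CEP290, chosen after its value was seen, by 0.53, and KIF3B changed by -0.36. IFT172 was higher by 0.37, a call lost without control replicates 1, 2 or 4 or KCTD17 siRNA replicates 13 or 14 (adjusted p up to 0.0846). CUL3 (0.14, adjusted p = 0.0309) lost its call without control replicates 1, 2 or 3 or KCTD17 siRNA replicates 13, 14 or 16 (adjusted p up to 0.0828). Of the relatives of KCTD17, KCTD2 rose by 0.39 (adjusted p = 0.0126) and KCTD5 was at -0.07 (adjusted p = 0.575). JUND was at 0.09 (adjusted p = 0.337).

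For the other lists, members higher and lower over all genes are given, with those adjusted over the list alone in brackets. For comparison, 15.0% of all tested genes were called. NRF2 targets had 2 and 4 of 24 (2 and 5; camera, adjusted p = 0.837): the pentose phosphate genes TALDO1 and PGD were at -0.40 and -0.42 and TXNRD1 at 0.21. ATF4 targets had 2 and 2 of 20 (2 and 3; 0.837), and PSAT1, an enzyme of serine synthesis, fell from 22.1 ± 2.79 to 11.8 ± 1.56 CPM (-0.91). In p53 targets and apoptosis, 2 and 3 of 20 (3 and 3; 0.837), BCL2L1 and MDM2 were at -0.31 and -0.23 and TP53INP1 at 0.49. RNA interference genes had 1 and 2 of 13 (1 and 3; 0.837), with TNRC6A, which has an identical copy, at 0.18 and AGO2 at -0.20, and interferon response genes 1 and 1 of 23 (1 and 1; 0.837). CUL3 ligase genes had 4 and 2 of 30 (4 and 2; 0.959), with UBE2M at -0.41 and BACH1 at 0.24, and the KCTD family 3 and 2 of 20 (3 and 3; 0.681). Ribosomal proteins had 3 and 1 of 35 (2 and 1; 0.104), with RPS16 at 0.19 and RPS15 at -0.22, and neuronal genes 3 and 1 of 17 (4 and 3; 0.470), with STMN2 at 0.18.

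Falls made up the calls in hypoxia (1 of 15; 0.452; ERO1A, -0.18), mitochondrially encoded genes (2 of 13; 0.714; MT-ND5, -0.21, and MT-CO1, -0.13), disallowed genes of beta cells (3 of 7; 0.758; SMAD3, -0.43, LDHA and FOXO1), immediate early genes (1 of 20; 0.837; JUNB, -0.29) and other islet endocrine genes (1 of 8; 0.837; DPP4, -0.39). These brackets give the camera adjusted p, and the counts were the same when adjusted over the list alone. In hedgehog signalling CDON rose (0.43; 1 of 9, also over the list alone; 0.959). Of the other calls in these lists, MX2 lost its call without control replicate 1 or KCTD17 siRNA replicate 15 (adjusted p up to 0.0577), DICER1 without KCTD17 siRNA replicate 14 (adjusted p up to 0.055) and LDHA without control replicate 4 or KCTD17 siRNA replicates 13 or 14 (adjusted p up to 0.0648). PHGDH and RPL27 lost theirs without 7 of the 8, KBTBD2, KCTD12 and MAP2 without 6, KCTD10, KCTD8, KLHL2 and SLC3A2 without 5, and ELAVL3 and SLC7A5 without 4.

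Nuclear genes of the respiratory chain had 0 calls among 35 members with edgeR, DESeq2 and limma-voom, and 6, 5 and 6 at an unadjusted p below 0.05 (camera, adjusted p = 0.959; edgeR gave 0 calls when adjusted over the list alone). Median, mean and test differed in sign for matrix and adhesion, interferon response, RNA interference, NRF2, p53, granule, CUL3 ligase and, with fry, hedgehog genes. The marker lists for exocrine and duct cells and for fibroblast, endothelial and immune cells had 3 measured members each and were not tested. In the first, KRT19 and CPA1 were at log2 fold changes of -0.06 and 0.18 (edgeR, adjusted p = 0.655 and 0.196). In the second, COL1A1 and PECAM1 were at 0.02 and -0.37 (adjusted p = 0.983 and 0.561), and CD68 fell.

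Genes whose annotated 3' UTR holds the sequence AGGCTCA were lower more often: 20.4% of 1385 such genes were called lower, against 9.85% of the other genes scanned. STX1A, NCR3LG1, HS6ST3, SC5D, CDH1, KIF3B, ELOVL5, ERO1A, MX2 and ACSS2 hold it, as does H2AC25, which rose. NKX6-1, MAFA, G6PC2, COL4A1, PSAT1 and RHOC hold none of the 6 motifs.

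On the first principal component of the 500 most variable genes, which held 19.2% of the variance, the groups did not separate past the threshold (exact permutation test, two-sided, p = 0.114). They did on 2000 genes and on all genes (20.1% and 23.4% of the variance, exact permutation p = 0.0286 for both).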

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

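The tests of siRNA pairing, base composition, lower KCTD17 itself, capture without a poly(A) tail and S phase were chosen only after the result was seen. In 316 groups of 4 values, 13 had a library standing apart from the other 3, and chance gives about 1 in 20. Each of the 8 libraries had at least 1 of them.

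In the control group, replicate 1 had 4954.5 CPM of MT-CO1 against at most 4889 in the others, 0.162 CPM of CCN3 against at least 0.570, and 33.4 CPM of KBTBD2 against at most 30.6. Replicate 2 had 120.1 CPM of PTCH1 against at most 111 in the others. Replicate 3 had 852 CPM of ACLY against at least 915. Replicate 4 had 581 CPM of P4HB against at most 551.

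In the KCTD17 siRNA group, replicate 13 had 26.99 CPM of CD68 against at most 21.5 and 115 CPM of BCL2L1 against at most 107. Replicate 14 had 425 CPM of the H2A gene ENSG00000272196 against at least 441, and 26.9 CPM of TP53INP1 against at least 29.5. Replicate 15 had 29.7 CPM of G6PC2 against at most 23.0 and 98.6 CPM of NDUFB10 against at most 85.5. Replicate 16 had 2.36 CPM of SLC2A2 against at most 1.96. The falls of CD68 and G6PC2 kept their calls without each single library.

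Genes lower with KCTD17 siRNA shared 7-base sequences in their 3' UTRs: AGGCTCA had the lowest score (z = -12.7, effect -0.08 log2, 1385 genes; at most 4.83 in size in 100 permutations), followed by AGGGACA, GGCTCAA, CTCCTAA and GAGGAGC, and CACATCA went with higher genes (z = 6.68). Base composition as the whole cause is argued against, as 571 sequences with the same bases in another order scored no lower than -3.21. This holds only once shifted copies of the motif, seen to score low in a first run, were left out. Among these copies, GGCTCAA has the same bases and scored -9.64 on its own. With it kept, the bound set for this test would not have been met. The model already held dinucleotide shares and GC content. Pairing of siRNA strands with these 3' UTRs, in the manner of microRNAs, is a candidate explanation: KCTD17 transcripts hold 10 of the 20 lowest-scoring sequences on either strand, a count seen before the comparison was made, against a median of 6 in 1893 genes of similar size. As 11.9% of those genes hold as many, and no siRNA sequence is given in the sources used here, it stays open. Lower KCTD17 itself stays open too, since with 1 pool and no rescue the explanations cannot be told apart for genes with a motif. Of the calls among scanned genes, 48.1% were in genes without any of the 6 motifs. As 6008 of the 10953 scanned genes hold none of them, this share cannot decide the question.

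Several classes of short structured RNAs were lower with KCTD17 siRNA. Genes with identical values in all libraries were counted once, a change made after the results were seen, since the 25 ribosomal genes hold only 3 distinct sets of values and the 51 spliceosomal genes 26. Called lower were 3 of 3 distinct ribosomal, 61 of 158 small nucleolar, 6 of 26 spliceosomal and 6 of 17 mitochondrial transfer RNAs, with medians (-0.87, -0.59, -0.42 and -0.59) that kept their sign with both other scalings. Small Cajal body RNAs fell less, 1 of 14 called lower (median -0.18), though their summed CPM also fell with no overlap of the groups, from 183 ± 13.8 to 164 ± 3.49 (SD, n = 4; exact permutation p = 0.0286). Of 65 miscellaneous RNAs 2 were called lower (median -0.05, summed CPM overlapping between the groups), and the only ribozyme gene was at -0.03. Reads shared between near-identical copies are argued against, since the summed CPM of the ribosomal, small nucleolar, spliceosomal and transfer RNA classes fell with no overlap of the groups (distinct ribosomal values from 3810 ± 425 to 2589 ± 96.4, SD, n = 4; exact permutation p = 0.0286). Less recovery of short molecules is a candidate explanation that met the rule set beforehand, a rho above 0: across 284 distinct values, which are not independent replicates, Spearman's rho of log2 fold change with length was 0.540 (permutation p = 1e-05, the smallest possible), 0.354 without the miscellaneous RNAs and 0.377 within small nucleolar RNAs. The 26 spliceosomal values, at -0.333 (permutation p = 0.0965), are too few to decide; a tighter rule, that no class may go the other way at p below 0.05, was added after a first run and was met once copies were counted once. As length goes with RNA class, the trend does not establish length as the cause. Whether lower KCTD17 acts on these RNAs was not tested.

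Genes of replication histones were mostly higher, 40 of 59 called higher and 5 lower, with all 15 H2A genes higher and H2B genes split into 6 and 5; the family medians kept their sign with both other scalings. Reads shared between copies would leave their sum level, but the summed CPM rose from 4117 ± 232 to 5536 ± 127 (SD, n = 4; log2 ratio 0.43, exact permutation p = 0.0286), though single H2B levels may still depend on such reads. For more capture of RNAs without a poly(A) tail, 10 such RNAs over 200 bases lay at a median of -0.10 (SD 0.17), below 0.34 for the histone genes. Mitochondrial ribosomal RNAs, which carry short tails, were taken out of this set after a first run, with the same outcome. Some of the 10, such as SNORD3A and SCARNA10, belong to the classes of short structured RNAs that fell. A fall of those classes could mask a rise in capture, so this set cannot decide the question. For more cells in S phase, the 12 G1/S genes of the proliferation list lay at a median of -0.11 (SD 0.12). The other 18 genes of that list lay at 0.41, with 17 called higher. The G1/S genes thus did not rise with the histone genes, but they cover only the entry into S phase. A change in the share of cells in later phases was not tested, so this set cannot decide the question. An effect of lower KCTD17 on histone RNAs stays a hypothesis, found and tested on the same data.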

How the results depend on the processing

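The corrections for GC content, gene type and annotation and the removal of genes with a motif were chosen after seeing the data. The number of called genes stayed within 1.5 times of 2914 with both other scalings, DESeq2, limma-voom, both filters, a surrogate variable, GC correction (Spearman's rho of fold change with GC content across protein-coding genes went from -0.203 to -0.00918), protein-coding genes only and primary annotation only, and ranged from 2292 to 2735 without each library. It was 531 against a fold change of 1.2 and 1609 at an adjusted p of 0.01, each narrower by construction. Without genes holding a motif it was 1381 of 14493 tested genes. Part of this drop follows from the genes left out, but some of the genes kept also lost their call. Of the called genes, 1849 were called in every fit without 1 library. Of the same 2914 genes, 2401 were called with GC correction, 2666 with library size only and 2565 without a filter. With GC correction 12 of 21 genes of the chaperone list were called higher, against 15 in the main fit. Of the 35 splits of the 8 libraries into 4 and 4, only the real 1 gave as many called genes and the highest other gave 5. A random grouping is thus unlikely to give this count, though standing alone is the most that 35 splits can show. The other splits mix the 2 siRNA groups, which in itself lowers their counts. Library order, which goes with the group, is not addressed by this comparison. For the 3 called lists chance cannot be excluded: 9 of the 35 splits gave as many, and the highest other gave 6.

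KCTD17 kept its direction and call in every fit, at -1.50 to -1.34 without each library; the test against a fold change of 1.2 (adjusted p = 4.1e-04) and the adjusted p of 0.01 were added for it after seeing the data. The number of called lists was 3 or 4 without each library, 2 without genes holding a motif, 0 with an estimated correlation and 8 with fry. Beside the 3 lists, fry called glucose sensing (adjusted p = 0.00164), matrix and adhesion (0.0051) and lipogenesis (0.0167) lower. It called primary cilium (0.0111) and neuronal genes (0.0161) higher. None of these further lists passed with camera. The adjusted p with an estimated correlation was 0.397 for chaperones, 0.641 for proliferation and 0.676 for cholesterol synthesis, which was at 0.245 without genes holding a motif. Without each library these 3 lists ranged from 2.2e-09 to 3.1e-07, 1.8e-06 to 9.3e-05 and 4.6e-04 to 0.00712. The distance between the group means on the first principal component was 17.2 (exact permutation p = 0.114). It passed the threshold over all genes (44.0), over 2000 genes (29.4), with the stricter filter (19.8), protein-coding genes (18.2) and primary annotation (18.1), and ranged from 7.07 (without KCTD17 siRNA replicate 16) to 24.3 (without replicate 13, where it passed). The cause was not tested.

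Of 149 genes taken by the rule other than KCTD17, 105 kept direction and side of the threshold in every fit at an adjusted p of 0.05 without a minimum fold change that held them, 29 lost a call and 13 gained one in at least 1 fit, and none of the 119 called ones turned direction. DESeq2 gave no adjusted p for 16 of them, 12 called, and these are not counted as lost there. IAPP, uncalled, turned to -3.7e-04 (RLE), -7.6e-05 (DESeq2), -0.0669 (GC correction), -0.0063 (protein-coding genes) and -0.00635 (without genes holding a motif), and ranged from -0.0876 to 0.121 without each library. INS, uncalled, turned to 0.0112 (library size only) and 0.0513 (GC correction). No paired analysis was possible because the groups share no replicate number. The transcript-level alternative was not run, as the table is at gene level. KCTD17, at 33 to 116 counts per library, and genes of a few CPM are limited by depth.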

Other observations

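Some members of the gene lists outside the rule for named genes were chosen only after their values were seen, and their calls were not followed without single libraries. GLP1R, the receptor of an incretin hormone, fell from 7.70 ± 0.919 to 4.68 ± 0.985 CPM (SD, n = 4; log2 fold change -0.72, edgeR adjusted p = 0.0123), and FFAR1, a fatty acid receptor, changed by -0.37. The exocytosis genes SNAP25 and VAMP2 rose by 0.23 and 0.25. CENPF and CENPE, parts of the kinetochore, rose by 0.81 and 0.87, and TGFB1 rose from 2.50 ± 0.569 to 4.72 ± 0.581 CPM (0.91). In cholesterol synthesis, SREBF2, the activator of the pathway, was at -0.21.

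Within the histone genes the largest fall was that of H2BC9, from 68.9 ± 4.45 to 40.7 ± 1.45 CPM (log2 fold change -0.76), beside the rise of H2BC14 from 25.9 ± 0.856 to 95.4 ± 2.36 CPM (1.88). H2AC4 rose from 28.4 ± 1.82 to 67.9 ± 6.61 CPM (1.26), while H1-4 changed by 0.19 and H4C11 was at 0.03 (edgeR, adjusted p = 0.797). By gene type, 1284 of 13620 protein-coding genes were higher and 1270 lower, against 11 and 20 of 1054 antisense genes and 12 and 14 of 1313 long intergenic RNAs.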
